A study of Drosophila melanogaster with 3 samples.

How the data were processed

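Chromatin immunoprecipitation with sequencing was done on whole prepupae of 1 transgenic line with GFP-tagged FoxP, in 3 biological replicates, per the labels. Fragments were made by sonication and were 200 to 800 bp long, per the labels. Peak lists were deposited in 2 genome builds, dm6 and dm3, with 5 lists per build. Per the file sheets deposited with the samples, each list was made from aligned reads and 1 shared control file per build, the replicate lists from the reads of that replicate and the pooled list from those of all 3. The aligner, the peak caller and its settings are not given in the sources used here. The thresholded list is named as the optimal result of an irreproducible discovery rate (IDR) step, and its regions were exactly the 2415 regions with the highest signal values of the pooled dm6 list (2379 in dm3). The pooled lists, and that of replicate 1, hold 30000 regions, including background regions that the IDR step takes as input, per the file sheets.

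Each region has a signal value deposited by the authors, a score with no stated scale, which was used to rank and describe regions within a list. It also has a deposited −log10 q-value, which was not used for ranking. In the thresholded dm6 list it ran from 1.86 to 2.07. Summits are the positions the authors gave. Of the dm6 thresholded regions, 91.2% had the same width of 416 bp. Read depths and libraries of control chromatin were not analysed here, so no interval for the depth of a region can be given. Intervals on shares cover counting error over regions or genes.

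Coordinates are dm6, 1-based. Chromosome arm lengths matched the reference genome (release 6) and gene models came from Ensembl release 115 (BDGP 6.54). The dm3 lists were compared with each other and never combined with dm6. The 20 dm6 thresholded regions on the mitochondrial genome were left out of the annotation, gene, motif and arm results after they had been seen, which leaves 2395 regions on 7 arms. No 2 replicates shared a region with identical coordinates and signal value.

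Replicates were compared over their 2415 best-ranked regions. A region was shared when it overlapped another by at least 1 bp. Chance was estimated by moving the regions of 1 list by 5000 to 50000 bp along their chromosome 100 times. For rank agreement the replicate region holding the thresholded summit, or the nearest within 200 bp, was used. Summits were put into 6 classes in the order promoter (within 500 bp of a start of a protein-coding gene), 5′ UTR, coding exon, 3′ UTR, intron, and outside protein-coding genes, and were compared with 1000 sets of moved summits. Genes with a promoter summit (1252 of 13968 protein-coding genes, 8.96%) were tested in 17 lists with 2-sided Fisher's exact tests. A summit between neighbouring starts counts for each gene. Neighbouring genes are not independent, which these tests do not model. Motifs were searched on both strands within 100 bp of each summit and in windows 1000 bp to either side, with an exact McNemar test against 1 window drawn per region. To compare summits with flanks at equal composition, each window was also shuffled 10 times with its dinucleotide counts kept. Arms were tested with exact binomial tests. P-values were adjusted by Benjamini-Hochberg within each family of 6 classes, 17 lists, 11 motifs or 7 arms, with a threshold of 0.05. All tests of the report were 2-sided.

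The tests, lists, alternatives and the rule for named genes were chosen before the data were examined, apart from those described here or below as chosen or added after. The rule takes the 20 best-ranked arm regions held by all 3 replicates, each with the nearest start of a protein-coding gene. It adds up to 4 members per list with a promoter summit, in order of signal value, all forkhead family genes with a promoter summit, and FoxP. Gene symbols of 3 list members were replaced by hand by the symbols of the annotation, before any enrichment was seen, and 1 forkhead symbol was not in the annotation. The alternatives were other counts of best-ranked regions, overlap rules, promoter and motif windows, control sets, the better-ranked part of the list, regions held by all 3 replicates, leaving out each replicate, and the dm3 lists. Leaving out a replicate kept the thresholded regions held by both others. Their calls, summits and signal values still came from the pooled reads of all 3. Results without mitochondrial regions were added after the data had been seen.

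The tests were run on simulated data. With 50.0% of 2400 regions planted as shared, 50.7% were found. Of 200 random gene lists, 0% passed, and of lists planted with an excess 100% passed. Genes with a summit and list members were drawn independently there. The simulated lists therefore do not cover neighbouring members, or long genes with several starts. The planted excess was large, so these lists do not show how often a smaller excess would be found. A motif planted at 10.0% of summits gave an excess of 9.96 percentage points over 20 made-up sequences, and 1 of 180 tests of motifs that were not planted passed. The made-up sequences had the same base composition at summits and in flanks. They therefore do not cover a difference in composition, which the data have. Analyses used Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1 and Matplotlib 3.10.9, with a random seed of 7.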

Results

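Binding of FoxP, the fly member of the FOXP branch of the forkhead transcription factors, was mapped in whole Drosophila melanogaster prepupae, the stage at which larval tissues are dismantled and adult structures form. The flies carried a FoxP transgene (also called fd85E) with eGFP fused to its C-terminal end, and chromatin was precipitated with an antibody against GFP. Males and females were pooled. The 3 biological replicates form 1 group, so the comparisons below are between replicates and between bound and other parts of the genome. Per build there were 5 peak lists: 1 per replicate, 1 for the pooled reads and a thresholded part of the pooled list. In dm6 coordinates the replicate lists held 30000, 24326 and 22698 regions for replicates 1, 2 and 3, the pooled list 30000 and the thresholded list 2415. The read depth of each library is unknown. Signal values are the authors' own, come from the pooled reads unless a replicate is named, and have no replicate error.

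The best-ranked region on the chromosome arms was in an intron of CG11050 (2L, 6612470 to 6612950), with a signal value of 2044. The next lay 22 bp from the start of Ugalt, a UDP-galactose transporter gene (X, 2703715 to 2704041), with 1867. Among the 20 best-ranked arm regions that all 3 replicates held, 11 summits were in promoters, 6 in introns and 3 outside protein-coding genes. The promoter summits belonged to Ugalt, CG14100, CenG1A, PNPase, Chro, CG1888, larp, Hsp27, CG18549, CG13921 and mRpL41. Of these, Hsp27 encodes a small heat shock protein (3L, 9383765 to 9384042, signal value 961), Chro a chromatin protein of interbands, and larp an RNA-binding protein that acts in translation. The summit at CenG1A (2L, 13835306 to 13835610, signal value 1216) was also within 500 bp of the start of mRpS23, and that at Chro of the start of Ssl1.

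The 6 intronic regions were nearest the starts of CG11050, cbt, osa, Lk6, CG32772 and Hr4. The region nearest cbt (2L, 480940 to 481250, signal value 1138) lay inside the gene ush, whose span also holds cbt. The region in osa, a gene for a subunit of the Brahma chromatin remodelling complex, was 13943 bp from the nearest start (3R, 17704272 to 17704545, signal value 1093). That in Lk6, a kinase gene, was at 3R, 11760901 to 11761173, with a signal value of 1092. Hr4, which encodes a nuclear receptor of the ecdysone cascade, held a region 9973 bp from a start (X, 1951792 to 1952033, signal value 873). The 3 regions outside protein-coding genes were nearest eEF1gamma, CG13323 and CG43245, at 5773, 11982 and 4652 bp. None of these 20 regions ranked below 80 in replicate 1, 24 in replicate 2 or 43 in replicate 3. Their median width was 271 bp, against 416 bp for all thresholded regions on the arms.

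The 2415 best-ranked regions of the replicates overlapped for most regions. Of those of replicate 1, 68.8% (95% Wilson interval 66.9 to 70.6) overlapped one of replicate 2 and 69.1% (67.2 to 70.9) one of replicate 3. Of those of replicate 2, 70.7% (68.8 to 72.5) overlapped one of replicate 3. After random moves of 1 list the means were 2.47%, 3.12% and 2.43%, and no move reached the observed share (2-sided permutation p = 0.0198 for each pair, the smallest that 100 moves give). Of the thresholded regions, 1415 (58.6%) overlapped a best-ranked region of all 3 replicates, 667 of 2, 311 of 1 and 22 of none. Replicates 1, 2 and 3 held 1960, 1997 and 1933 of them. Across thresholded regions, which are not independent replicates, the Spearman correlation between the signal values of 2 replicates was 0.569 for replicates 1 and 2 (2350 regions), 0.585 for 1 and 3 (2375 regions) and 0.608 for 2 and 3 (2379 regions). The count held by all 3 replicates was 748 with the 1207 best-ranked regions of each and 2137 with 4830. This change is largely built in, as the 2415 thresholded regions stayed fixed while the replicate lists changed in length. The overlap of pairs was 69.2% to 71.7% with 1207 regions and 66.9% to 67.9% with 4830.

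Thresholded summits lay at promoters of protein-coding genes about 3 times as often as moved summits and were nearly absent from coding exons outside promoters. Coding sequence within 500 bp of a start was counted as promoter. On the arms, 1089 of 2395 summits (45.5%, 95% Wilson interval 43.5 to 47.5) were within 500 bp of a start, against 14.8% ± 0.705 (SD of 1000 moves). In coding exons there were 4 summits (0.167%) against 18.7%, and in 3′ UTRs 14 (0.585%) against 5.96%. Outside protein-coding genes there were 358 (14.9%) against 19.9%. For these 4 classes the permutation p was 0.002, the smallest that the moves give, and 0.003 after Benjamini-Hochberg adjustment over 6 classes. Introns held 910 summits (38.0% against 39.7%, adjusted permutation p = 0.0935) and 5′ UTRs 20 (0.835% against 1.01%, adjusted permutation p = 0.458, and 0.0360 with a promoter window of 1000 bp). The intron deficit passed with a promoter window of 1000 bp (adjusted permutation p = 0.00240), starts of all gene types (0.0144), the better-ranked 1197 regions (0.0408) and without replicate 2 (0.0120). With a promoter window of 200 bp, summits were 3.68 percentage points more frequent in introns than moved summits (adjusted permutation p = 0.00300), and the deficit outside protein-coding genes no longer passed (adjusted permutation p = 0.0647).

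**Figure D1:**
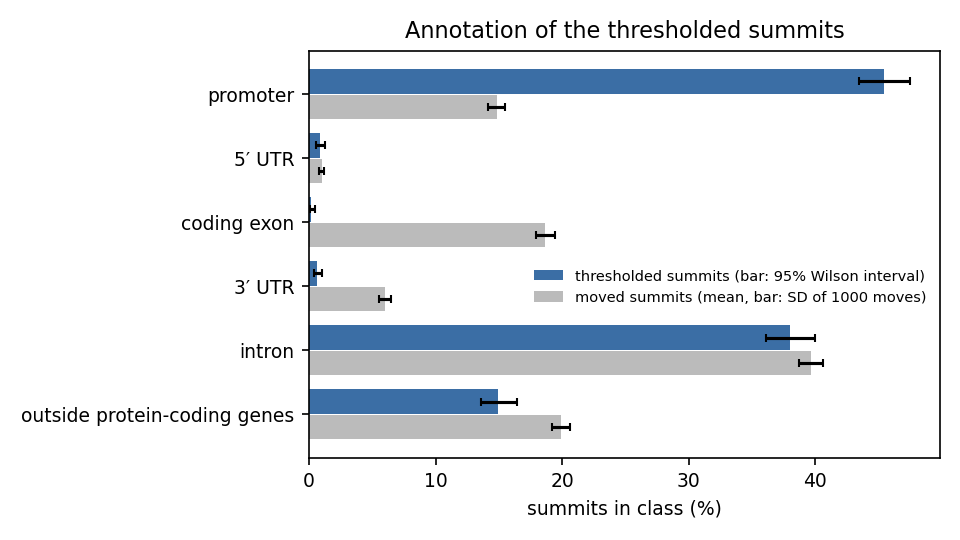
Share of thresholded summits on the chromosome arms (horizontal axis, percent) in each annotation class, beside the mean of 1000 sets of moved summits. Promoters held 45.5% of summits against 14.8% of moved ones, and coding exons 0.167% against 18.7%. Error bars are 95% Wilson intervals for the observed shares and SDs for the moved ones.

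Genes for cytoplasmic ribosomal proteins had promoter summits far more often than other genes. Of 92 members, 48 (52.2%) had one, against 8.68% of the other protein-coding genes (odds ratio 11.5, 95% interval 7.43 to 17.8, Fisher's exact test with Benjamini-Hochberg adjustment over 17 lists, adjusted p = 2.96e-25). The highest signal values were at RpL41 (425), RpL14 (406), RpL7 (398) and RpL24 (378). Of the 48, 34 rested on a region held by all 3 replicates. The proteasome list had summits at 2 of 48 members, Rpn5 (257) and Rpn13 (152), with an odds ratio of 0.441 (0.0518 to 1.69, exact adjusted p = 0.54). It holds 16 paralogs named R or T, and without them, an alternative chosen after seeing the data, the odds ratio was 0.677 (0.0783 to 2.67).

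Heat shock and stress genes also had promoter summits more often, at 8 of 21 members (38.1%, odds ratio 6.28, 2.25 to 16.4, exact adjusted p = 0.00107). They included Hsp27, the chaperone gene Hsp83 (467), the small heat shock gene Hsp26 (363) and puc (345), a phosphatase gene of the JNK pathway. Hsp22, Hsp26 and Hsp27 are neighbours on 3L and each had its own region. Of the 8, 5 rested on a region held by all 3 replicates. The excess of 29.2 percentage points fell to 17.6, 17.9 and 22.5 without replicate 1, 2 or 3 and still passed (exact adjusted p = 0.0230, 0.0222 and 0.00731). These settings keep fewer regions, which also lowers the share of other genes with a summit. With the better-ranked 1197 regions alone the excess was 14.1 percentage points and did not pass (exact adjusted p = 0.0647).

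Ecdysone response genes, which the steroid pulses of metamorphosis control, had promoter summits at 10 of 28 members (35.7%, odds ratio 5.68, 2.34 to 13.01, exact adjusted p = 5.33e-04). The highest were Eip93F (3R, 21972096 to 21972511, signal value 342), Eip75B (3L, 17999546 to 17999961, 283), Eip74EF (3L, 17619329 to 17619744, 221) and tai (189), which encodes a coactivator of the ecdysone receptor. Of the 10, 4 rested on a region held by all 3 replicates. The excess fell from 26.8 percentage points to 18.8, 15.6 and 15.3 without replicate 1, 2 or 3 and still passed (exact adjusted p = 0.00745, 0.0218 and 0.0200). Here too fewer regions were kept and the share of other genes with a summit was lower. Many of these genes are long and have several starts. Random lists matched on gene length and number of starts had summits at 20.8% of their members (adjusted permutation p = 0.233), and with the better-ranked 1197 regions the adjusted p was 0.398.

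No promoter summit was found at 179 chemosensory receptor genes, a list fixed in advance as one of largely silent genes, a count that allows a share of up to 1.68% (odds ratio 0, upper 95% limit 0.209, exact adjusted p = 7.57e-07). Among the 122 genes of the cuticle list there was 1, Cpr72Eb (224, odds ratio 0.0832, 0.00209 to 0.473, exact adjusted p = 0.00107). The list holds Cpr, a P450 reductase gene that its name pattern brought in, and without it the adjusted p was 0.00103 (exact, chosen after seeing the data). The cuticle deficit did not pass against matched lists, which had summits at 4.79% of members (adjusted permutation p = 0.142), with the better-ranked 1197 regions (exact adjusted p = 0.0939), or with regions held by all 3 replicates (exact adjusted p = 0.0628). When 1 replicate was left out the differences from other genes, in percentage points, moved from -9.08 to between -6.30 and -5.98 (chemosensory) and from -8.22 to between -5.45 and -5.13 (cuticle), and both still passed. The counts in both lists stayed the same, and the chemosensory count of 0 could not fall. These moves therefore come from the share of other genes, which falls as fewer regions are kept.

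The other 12 lists did not pass. Notch pathway genes had promoter summits at 6 of 27 members (exact adjusted p = 0.0835), the highest at numb (337), aph-1 (250), mam (244) and E(spl)mdelta-HLH (224), and all 6 rested on regions held by all 3 replicates. With regions of that kind alone the list passed (exact adjusted p = 0.0132), as it did when any 1 replicate was left out (exact adjusted p = 0.0200 to 0.0230) and with a window of 1000 bp (exact adjusted p = 0.0172). It did not pass with a window of 200 bp (excess 1.29 percentage points, exact adjusted p = 0.882), against matched lists (adjusted permutation p = 0.151) or with the better-ranked 1197 regions (exact adjusted p = 0.0572). Apoptosis and autophagy genes had summits at 5 of 21 (exact adjusted p = 0.0843), among them Atg17 (296), Atg2 (247), Atg18a (237) and the death gene hid (207). The excess was 3.41 percentage points with a window of 200 bp (exact adjusted p = 0.701) and did not pass against matched lists (adjusted permutation p = 0.241). Of 39 developmental transcription factor genes, 5 had one, with Dll (787) and Sox14 (723) the highest, followed by pnt (199) and sd (169). Of 36 axon guidance genes 5 had one, among them Ten-m (221), Fas2 (207), Ten-a (183) and PlexA (157), and of 37 synaptic and excitability genes 2, elav (469) and Syx1A (168). Both had an interval of the odds ratio that includes 1 (0.497 to 4.27 and 0.0675 to 2.26). Counting a summit inside a gene or up to 1000 bp upstream of it, the axon guidance list passed (exact adjusted p = 2.75e-04), and so did the Notch list (exact adjusted p = 3.77e-05) and the apoptosis and autophagy list (exact adjusted p = 0.0309). This count favours long genes. Against lists matched on length and starts and counted the same way, a comparison chosen after seeing the data, the Notch list passed (48.1% against 14.2%, adjusted permutation p = 0.00113), as did the ecdysone list (67.9% against 33.7%, adjusted permutation p = 0.00340). The axon guidance list (38.9% against 28.5%, adjusted permutation p = 0.375) and the apoptosis and autophagy list (adjusted permutation p = 0.118) did not, and the synaptic list had fewer (8.11% against 28.9%, adjusted permutation p = 0.0102). Many members of the Notch list are E(spl) genes that lie close together on 3R. The matched draws treat them as independent, so the p-value of that list may be too small. Muscle genes had summits at 3 of 23 (Msp300, 293; sd; Zasp52, 162), fat body genes at 1 of 18 (Lpin, 645), haemocyte genes at 1 of 15 (ush, 166), and midgut and tracheal genes at none of 16 and 12, which allows shares of up to 18.8% and 25%. Chromatin came from whole prepupae, so tissues were not separated. A low count in a list of neuronal or other tissue genes therefore cannot be read as a lack of binding in that tissue.

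Of the 17 forkhead family genes, 3 had promoter summits (exact adjusted p = 0.406): fkh (3R, 28585285 to 28585700, signal value 253), CHES-1-like (X, 7696832 to 7697247, 248) and FoxK (3L, 11120293 to 11120708, 181). The mitochondrial ribosomal protein gene mRpL2 had the same value as FoxK (181.283 for both), as when 1 summit counts for both genes. FoxP itself (3R, 9726020 to 9730872, minus strand) had no promoter summit. No thresholded region lay in the gene or within 20000 bp of it. The best region of the pooled list there ranked 5390 of 30000 (signal value 85.9) and was nearest Pnn, and the best of replicates 1, 2 and 3 ranked 8152, 4761 and 4787.

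**Figure D2:**
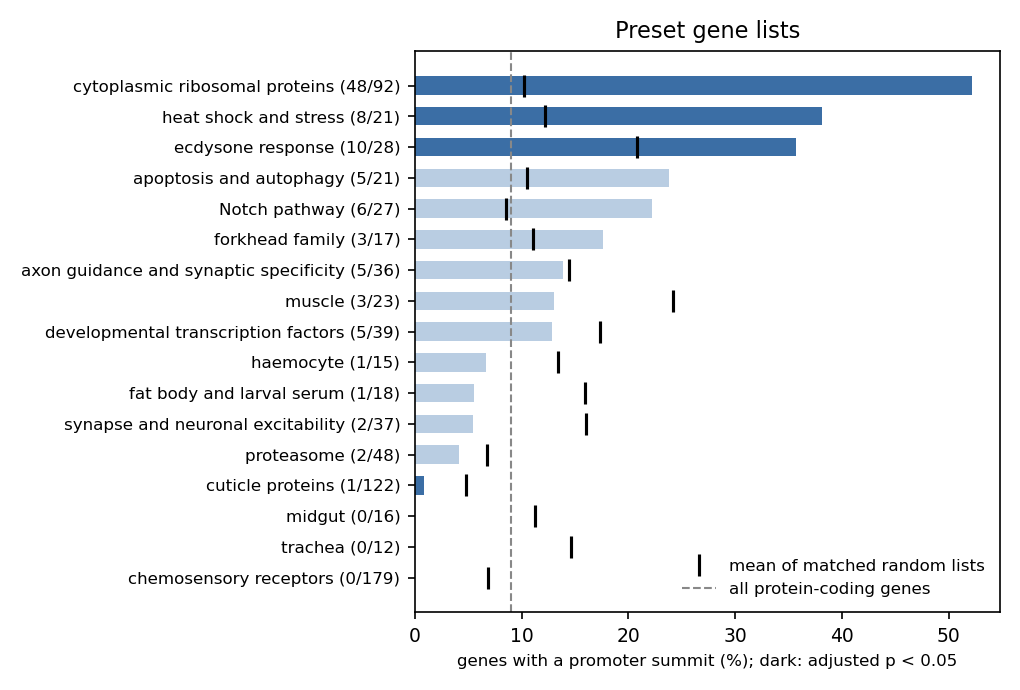
Share of genes with a promoter summit (horizontal axis, percent) in each of 17 gene lists, with counts beside the names. Dark bars passed the adjusted Fisher's exact test, vertical ticks mark the mean of matched random lists, and the dashed line marks the 8.96% of all protein-coding genes. Cytoplasmic ribosomal protein genes reached 52.2%, and chemosensory receptor genes, which also passed, had none and so no bar.

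The forkhead consensus RYAAAYA was found within 100 bp of 50.8% of summits (95% Wilson interval 48.8 to 52.8) and in 43.4% of flanking windows (exact McNemar test, adjusted p = 5.18e-07). Its mirror form, with the same bases in reverse order, rose from 41.3% to 48.4%, but 4 of its 8 sequences also match RYAAAYA, so it is no separate control. The stricter form TRTTTAC was found at 12.5% against 10.5% (exact McNemar test, adjusted p = 0.0217) and its mirror at 12.1% against 11.6%. The excess of TRTTTAC was 1.61 percentage points larger than that of its mirror, with a 95% bootstrap interval that includes 0 (-0.585 to 3.90). The strict form did not pass with regions held by all 3 replicates (exact adjusted p = 0.337), nor with the regions held by both remaining replicates after any 1 was left out (exact adjusted p = 0.0830 to 0.611).

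Sites of DREF, M1BP and BEAF-32 were enriched relative to flanks but present at few summits. The DREF consensus was at 1.84% of summits against 0.522% of flanks (exact adjusted p = 1.73e-04), the M1BP consensus at 0.919% against 0.271% (exact adjusted p = 0.00682) and the BEAF-32 pair, which overlaps that of DREF, at 5.85% against 3.92% (exact adjusted p = 0.00341), all by exact McNemar tests. Away from any start these 3 were less frequent than in flanks, by differences that did not pass, and none of them passed with regions held by all 3 replicates. Without replicate 1, DREF had an excess of 1.03 percentage points (exact adjusted p = 0.0508), and M1BP and BEAF-32 did not pass whichever replicate was left out (excess 0.305 to 0.363 and 1.22 to 1.79 percentage points). GAGAG, the core of GAGA factor sites, was at 33.3% against 24.3% (exact adjusted p = 4.03e-13). It reads the same in mirror form. It exceeded dinucleotide-shuffled copies of the same windows by 14.7 percentage points at summits and 3.02 in flanks, a difference of 11.7 (95% bootstrap interval 9.64 to 13.7), a test chosen after the motif results had been seen. The TATA box rose from 8.68% to 12.3% (exact adjusted p = 6.73e-04) while its mirror rose from 14.2% to 20.8%. E-boxes were less frequent at summits, at 60.5% against 64.8% (exact adjusted p = 0.0466), but more frequent than in shuffled windows. Neither the TATA box nor the E-box passed without replicate 1 (exact adjusted p = 0.344 and 0.278). No ecdysone receptor repeat was found at 2395 summits, and AP-1 and Zelda sites did not pass (exact adjusted p = 0.267 and 0.657).

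**Figure D3:**
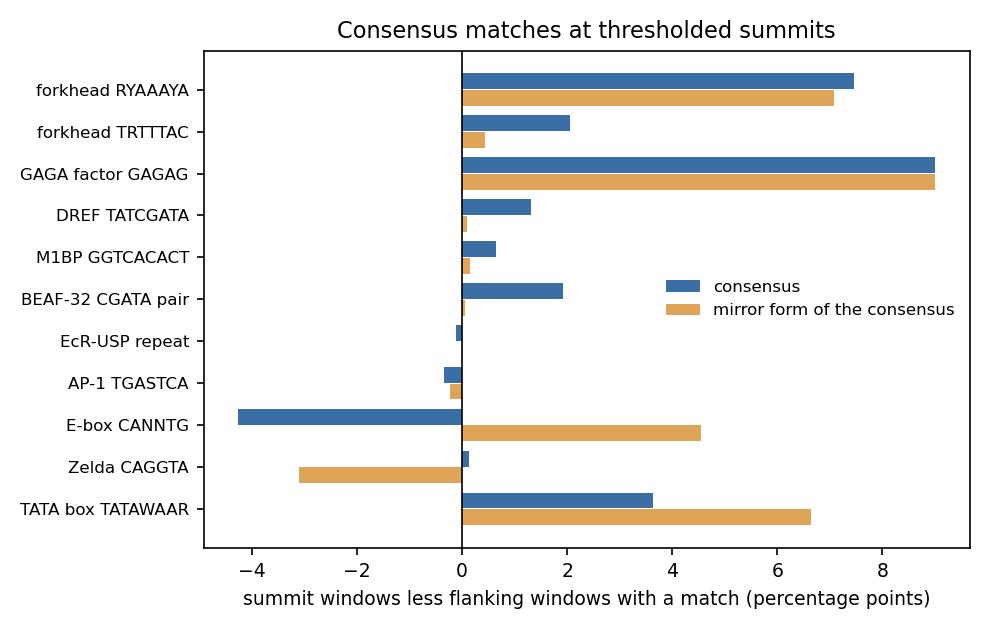
Share of windows with a match at summits less that in flanking windows (horizontal axis, percentage points) for 11 consensus sequences and for their mirror forms. For BEAF-32 the mirror search left out the pair that the consensus search allowed, so its mirror bar is no control. The forkhead consensus RYAAAYA and its mirror, which share 4 of 8 sequences, rose by 7.45 and 7.08 percentage points.

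Arm 4, the small and largely heterochromatic dot chromosome, held 5 thresholded regions against 23.5 expected from its length (ratio 0.213, exact binomial test, adjusted p = 3.39e-05) and 17.3 expected from its starts (ratio 0.289, exact adjusted p = 0.00351). By starts the deficit did not pass with the better-ranked 1197 regions (ratio 0.231, exact adjusted p = 0.0548). Without replicate 2 the ratios were 0.127 by length and 0.173 by starts, and both still passed. The 5 regions were nearest RpS3A, Cals, ci, gw and PlexA, and apart from those the other rules name, these genes were chosen after their values were seen. Arm 3L held 538 against 489 by length (ratio 1.10, exact adjusted p = 0.0349) and 462 by starts (ratio 1.17, exact adjusted p = 7.10e-04). The length-based excess of 3L did not pass with the better-ranked 1197 regions (exact adjusted p = 0.199), regions held by all 3 replicates (exact adjusted p = 0.121), the dm3 lists (exact adjusted p = 0.0577), without replicate 1 (exact adjusted p = 0.143) or without replicate 3 (exact adjusted p = 0.165). The Y held none against 63.9 by length (exact adjusted p = 1.07e-27) and 2.81 by starts (exact adjusted p = 0.220), but also only 2 regions of the pooled list, 0.00667% against 2.67% of arm length. Arm X held 427 against 410 by length (exact adjusted p = 0.624), and passed by starts without replicate 1 (ratio 1.14, exact adjusted p = 0.0241). Arms 2L, 2R and 3R did not pass.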

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

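The tests of base composition, abundant transcription and callable regions were chosen after the results they bear on had been seen. Lists matched on length and starts were planned before the data were seen, and their reading was written after. The tests of forkhead sites outside promoters and of GC content on arm 4 were written before theirs. The dm6 thresholded list held 20 regions on the mitochondrial genome, in data that the annotation results do not use, and the highest signal value among them was 5821, against 2044 for the best arm region. Replicates 1 and 3 had 25 and 20 such regions in dm6 and replicate 2 had none. In dm3 the thresholded list held 2, and replicates 1, 2 and 3 held 5, 2 and 4. No explanation was tested.

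The excess of the forkhead consensus at summits was weighed against base composition. RYAAAYA exceeded dinucleotide-shuffled copies of the same windows by 10.3 percentage points at summits and 10.2 in flanks, a difference of 0.0960 (95% bootstrap interval -2.29 to 2.49), so composition may account for its rise over flanks: the median GC content was 36.8% at summits and 41.8% in flanks. TRTTTAC exceeded its shuffled copies by 3.47 percentage points at summits and 3.59 in flanks, a difference of -0.119 (95% bootstrap interval -1.74 to 1.56). Composition may therefore account for the rise of TRTTTAC as well. The planned comparison of summits alone with shuffled windows gave 10.4 percentage points for RYAAAYA (exact McNemar test, adjusted p = 5.67e-14) and 3.47 for TRTTTAC (exact adjusted p = 1.85e-04), which does not set summits apart from flanks. Outside promoters (1306 summits) the excess of TRTTTAC was 0.689 percentage points larger than that of its mirror (-2.37 to 3.75), which leaves forkhead sites there open. Indirect recruitment by other proteins was not tested.

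The summits at ribosomal protein promoters were weighed against gene length and number of starts, and against transcription in general. Lists matched on starts and length had promoter summits at 10.2% of members against 52.2%, which argues against these 2 traits as the cause. Other traits of gene structure were not matched. In a list of other genes known in general to be abundantly and broadly transcribed, whose transcription in prepupae was not measured here, 15 of 39 (38.5%) had a promoter summit, against 8.59% of all remaining genes (Fisher's exact test, p = 3.72e-07), and the difference from ribosomal protein genes had an interval of -32.0 to 5.24 percentage points. For 9 of the 39, results had been seen when the list was written, and of the other 30 genes 10 (33.3%) had a promoter summit (-37.7 to 1.89). Other families of broad use did not pass and had upper limits of the odds ratio below the 7.43 of the ribosomal lower limit: the proteasome without paralogs named R or T (6.25%, upper limit 2.67), mitochondrial ribosomal proteins (13.7%, 3.18) and aminoacyl-tRNA synthetases (11.4%, 3.72), which argues against broad transcription alone. Abundant transcription, as a trait that favours either FoxP binding or unspecific precipitation at open promoters, stays a candidate explanation, and precipitation from flies without the tag, which could separate these, was not analysed here.

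The low count on arm 4 was weighed against detection. Arm 4 held 1.06% of the pooled list on the arms against 0.980% of arm length, which argues against a lack of callable regions. Regions of other arms matched on GC content gave 23.7 thresholded regions among 317 (95% range 15 to 33) against the observed 5, which argues against GC content. The chromatin state of this arm stays open as a possible explanation and was not tested.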

How the results depend on the processing

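Of 449 values under an alternative, 356 kept their direction and side of the threshold or stayed within the spread. The overlap of replicates, the promoter excess, and the lists of cytoplasmic ribosomal proteins and chemosensory receptors did so under every alternative run, the first also without mitochondrial regions, an alternative chosen after seeing the data. Fewer regions enter some alternatives: 1197 better-ranked, 1415 held by all 3 replicates, 1227 away from any start, and 1651, 1601 and 1640 without replicate 1, 2 or 3. A smaller difference there may come from the shorter list rather than from 1 replicate. The cause of a change was not tested. Unknown read depth limits what the absence of a region shows. The Spearman correlation of signal values became 0.601, 0.627 and 0.646 for replicates 1 and 2, 1 and 3, and 2 and 3 with the best overlapping region, and 0.591 and 0.647 for the first and last pair with better-ranked regions. The count held by all replicates was 748 with 1207 best-ranked regions and 2137 with 4830, a change largely set by the length of the replicate lists. Differences from moved summits, in percentage points, became 0.482 (5′ UTR), 3.68 (introns, passing) and -1.46 (outside genes) with a 200 bp promoter window, and -0.310 (5′ UTR) and -4.71 (introns) with 1000 bp. Both of the latter passed, as did introns with starts of all gene types (-2.36), better-ranked regions (-2.72) and without replicate 2 (-2.82 to -1.90 when a replicate was left out). A circular shift gave 0.0480 for 5′ UTRs and -15.4 outside genes, where the main setting gave -4.94 and both passed. Differences between a list and other genes, in percentage points, became -1.78 (muscle), 0.546 (haemocyte) and -0.996 (developmental factors) with a 200 bp window, and 18.9 (Notch) with 1000 bp. Counting summits upstream or inside genes they became 25.8 (axon guidance), 3.53 (fat body), 20.2 (trachea), 35.1 (Notch) and 20.2 (apoptosis and autophagy), and 8 lists passed. Counted so but against matched lists, chosen after seeing the data, they were -20.8 (synapse, passing), 33.9 (Notch, passing), -12.3 (muscle), 4.13 (trachea), -9.04 (developmental factors) and -4.59 (cuticle, not passing). Against matched lists, 3 passed, with 14.9 (ecdysone), -0.581 (axon guidance), -11.1 (muscle), -4.52 (developmental factors) and -3.97 (cuticle). With better-ranked regions 2 passed, with 5.71 (ecdysone), -0.672 (muscle), 0.538 (fat body), 14.1 (heat shock) and -4.24 (cuticle). With regions held by all replicates they were 0.315 (fat body), 17.0 (Notch) and -4.46 (cuticle). Leaving out a replicate gave 16.03 to 16.35 for Notch, past the threshold each time, and -6.23 to 0.761 for haemocyte genes, positive without replicate 2. Motif differences from controls, in percentage points, became -0.835 (E-box) with 200 bp windows, and 3.72 (E-box) and -1.25 (Zelda) against shuffled windows. Away from starts they were 1.51 (TRTTTAC), -0.285 (DREF), -0.122 (M1BP), -1.14 (BEAF-32), 0.122 (AP-1) and 2.89 (TATA). With better-ranked regions they were 0.209 (M1BP), 0.835 (BEAF-32), 0.251 (AP-1) and -3.43 (E-box), and with regions held by all replicates 1.70 (TRTTTAC), 0.954 (DREF), 0.247 (M1BP) and 1.24 (BEAF-32). Leaving out a replicate gave 1.22 to 2.19 (TRTTTAC), 0.305 to 0.363 (M1BP) and 1.22 to 1.79 (BEAF-32), never past the threshold. It gave 1.03 to 1.09 (DREF), -4.09 to -3.51 (E-box) and 2.21 to 3.03 (TATA), which did not pass without replicate 1. Ratios by length in dm3 were 0.928 (2L), 1.10 (3L, not passing) and 0.954 (X). With better-ranked regions they were 0.991 (2R), 1.10 (3L, not passing) and 1.02 (3R) by length, and 1.01 (3R) and 0.231 (arm 4, not passing) by starts, and with regions held by all replicates 1.10 (3L, not passing) by length. Leaving out a replicate gave 0.985 to 1.05 (2L, below 1 without replicate 1) and 1.08 to 1.15 (3L, not passing without replicates 1 or 3) by length, and 1.04 to 1.14 (X, passing without replicate 1) by starts.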

Other observations

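Gene families chosen after the lists above had been seen were tested in the same way, with adjustment over 5 families. Histone genes had a promoter summit at 1 of 115 members, His3.3B, which lies outside the repeated histone cluster (odds ratio 0.0884, 95% interval 0.00222 to 0.503, Fisher's exact test, adjusted p = 0.00217). How reads from the repeated copies were placed is not given. The lack of regions in the cluster therefore cannot be read as a lack of binding, and the test treats the copies as separate genes. Odorant-binding protein genes had none of 51 (exact adjusted p = 0.0326). Of 51 translation factor genes 8 had one (15.7%, exact adjusted p = 0.188), with the highest signal values at eIF6 (655) and eIF4EHP (598). Of 35 aminoacyl-tRNA synthetase genes 4 had one (11.4%, exact adjusted p = 0.551), among them GluProRS (194) and IleRS (183).

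The hypothesis that genes for mitochondrial ribosomal proteins share the excess of the cytoplasmic ones was tested after mRpS23 and mRpL41 had been seen among the best-ranked regions. Of 73 such genes 10 had a promoter summit (13.7%), with an odds ratio of 1.62 (95% interval 0.738 to 3.18, Fisher's exact test, p = 0.151). This excludes an excess as large as that of the cytoplasmic genes, whose odds ratio was 11.5 with a lower limit of 7.43, and leaves a smaller one open. Of the 10 signal values, 4 were above the highest of the cytoplasmic genes, RpL41 (425): mRpS23 (1216, at a summit shared with CenG1A), mRpL41 (884), mRpS10 (738) and mRpL23 (529). The other 6 were 153 to 242, and among them mRpL2 had the same value as the forkhead gene FoxK (181).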
